A study of Mus musculus with 9 samples.

How the data were processed

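RNA of 9 samples was measured on Affymetrix Mouse Genome 430 2.0 arrays, with biotin-labelled cRNA made from 100 ng of total RNA, per the labels' protocols. The values are intensity values of probe sets on a linear scale, as deposited by the authors. The tool that made them is not given in the sources used here. On every array the mean signal, leaving out the lowest and highest 2% of probe sets, was 1500, as scaling to a common target gives. Such scaling sets aside any difference in total RNA between samples. Median signals lay between 264.7 and 287.4. The ratio of 3' to 5' Gapdh signal lay between 0.93 and 1.14, and that of Actb was 1.87 to 1.88 in wild-type NSC, 1.49 to 1.67 in Nf1-null NSC and 1.73 to 1.85 in glioma stem cells.

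Of 45101 probe sets, 64 were controls. Of the rest, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none, and probe sets without exactly 1 symbol stayed out of the main tests. Symbols were looked up through Entrez identifiers in a RefSeq gene table for 34741 probe sets, and 0 changed. Of several probe sets of a gene the brightest by mean over the 9 arrays stood for the gene, which applied to 9010 of 18193 genes. Other probe sets of a gene can disagree, as for Nf1, whose other 2 probe sets were dim. The mean of all probe sets was run as an alternative.

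Values were turned into log2(value + 1), so fold changes are on that scale and depend on the pseudocount for dim genes. Groups and replicate numbers came from the labels, whose design text speaks of 3 independent cultures for the NSC and does not say this of the glioma stem cells. All 9 arrays entered 1 linear model with 3 group means in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation without a mean-variance trend, 6 residual and 1.63 prior degrees of freedom. Each of the 3 contrasts was tested two-sided at a Benjamini-Hochberg adjusted p under 0.05. The contrast of glioma stem cells with Nf1-null NSC is itself the test of the difference between the changes of each against wild-type NSC. Fold values in the text are 2 to the power of the log2 difference of group means, and errors of those differences are moderated standard errors.

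Lists of genes, 37 in number, were fixed before the data were examined, and 996 of their 1100 genes were measured. They were tested with camera at a preset correlation of 0.01, beside an estimated correlation and the rotation test fry. Genes named in the text followed a rule fixed in advance. It took the 10 largest rises and the 10 largest falls per comparison among genes past the threshold without overlap of the groups, leaving out clone and model names, olfactory and vomeronasal receptor genes, microRNAs and other small RNAs, and immunoglobulin and T cell receptor segments. It added up to 4 members with the smallest adjusted p from each list that passed its test or had at least 3 members past the threshold, and always Nf1 and Abcg1. Abcg1 was put in from prior knowledge of work that may have used these samples, and the labels do not name it. Xist, the Y-linked genes, Pdgfra, Pxdc1, Lpl, Fgf1, Siglech, Abcb8 and Abcc5 were named outside the rule, after their values were seen. So were values of rule-named genes in a comparison other than the one that named them, such as Brinp3 between the NSC groups.

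Whether equal replicate numbers pair the arrays was checked by the correlation, across the brighter 9097 genes, of deviations from group means. Same-numbered wild-type and Nf1-null NSC arrays correlated at 0.64, 0.24 and 0.59, all above 0.1, and at 0.13, 0.05 and 0.17 over all genes. Differently numbered pairs of these arrays lay between -0.54 and -0.02 across the brighter genes. Deviations cancel out within a group, so these negative values follow largely from the positive ones and are no separate support for pairing. The labels do not state that a number marks a shared culture, so the pairing of the NSC comes from these data. Xist signals matched it, at 587.7 and 385.6 on the NSC arrays numbered 3 of the wild-type and Nf1-null groups and at 30974.5 or more on the other 4. Glioma stem cells came from other mice, and their same-numbered correlations were 0.24, 0.05 and 0.20 with wild-type NSC and 0.30, 0.12 and 0.11 with Nf1-null NSC. The last 3 values are above 0.1, but differently numbered pairs of these groups reached 0.11 and the values over all genes were 0.08, 0.04 and 0.01, so the blocked counts are given beside that comparison without reading them as paired. The main model has no block, and the block was run as an alternative.

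The model was tested on simulated arrays with the real means and spreads. These arrays were simulated as independent, without the pairing of the NSC arrays. Genes to be changed were drawn only from those with a mean log2 signal above 6.41, the limit of the dimmest bin. The simulated comparison of Nf1-null with wild-type NSC was tested over 18193 genes. It recovered 22.4% of the genes changed by 1 on the log2 scale, 79.1% of those changed by 2 and 89.4% of those changed by 4. Over the 9097 brighter genes these shares were 64.3%, 93.5% and 100%. The shares do not cover the dimmest bin of genes, nor arrays that are paired. The real comparison of these groups gave 0 calls over all genes. False calls numbered 6 of 133 calls over all genes and 4 of 114 over the brighter genes. In 20 runs with no change in any group, 1 had a gene called between glioma stem cells and wild-type NSC. The median spread between replicates was 1.12, 0.50, 0.26 and 0.20 on the log2 scale in 4 equal bins of genes, from the dimmest to the brightest, so dim genes carry most of the noise.

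Alternatives planned in advance were quantile normalization, a shift of each array to the same median, other summaries of probe sets, filters on dim genes and other variance priors. Array weights, fits of 6 arrays, the replicate block, each array left out, other thresholds, a pseudocount of 16 and an ordinary (unmoderated) per-gene linear-model test were planned as well. Combinations chosen after seeing the data are named as such. Figures were drawn with matplotlib 3.10.9.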

Results

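Gene expression was measured on 9 Affymetrix mouse arrays, 3 per group, in cultures kept in low-attachment dishes with 20 ng/ml FGF and 20 ng/ml EGF. Wild-type neural stem cells (NSC) came from the third ventricle of pups at postnatal day 1 that carried floxed Nf1 alleles, and had received a control LacZ virus. Nf1-null NSC were cells of the same kind that had received a Cre virus, which removes the floxed part of Nf1, the gene of the Ras inhibitor neurofibromin. Glioma stem cells were cultured from optic gliomas of 3-month-old mice of the genotype Nf1+/- GFAP CKO. The glioma stem cells therefore differed from both NSC groups in tumour origin, age, tissue, virus and background genotype together. Signals of Xist and the Y-linked genes, given below, also differed between arrays, so sex make-up is a further difference. The labels speak of separate cultures for the NSC and do not say whether the 3 glioma stem cell arrays came from separate tumours. The p-values therefore measure only the spread between these samples. The number of arrays, 3 per group, limited the precision of every comparison.

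Groups did not overlap along the first principal component of the brighter genes, the 9097 genes with a mean log2 signal of at least 9.27. This component held 51.5% of the variance and ran from wild-type NSC (-44.84 to -29.85) through Nf1-null NSC (-13.78 to 7.82) to glioma stem cells (25.28 to 48.81). Glioma stem cell array 1, at 25.28, stood apart from arrays 2 and 3 of its group, at 46.47 and 48.81. Across the brighter genes, arrays 2 and 3 correlated at 0.989, and array 1 correlated with them at 0.950 and 0.944. Nf1-null NSC array 2 likewise correlated with arrays 1 and 3 of its group at 0.947 and 0.938. Nf1-null NSC array 3 correlated at 0.956 with wild-type NSC array 3, and at 0.954 and 0.938 within its own group. Nf1-null NSC array 1 correlated at 0.952 with wild-type NSC array 1 and at 0.944 with glioma stem cell array 1. Within its own group it correlated at 0.947 and 0.954. Some arrays were thus as close to an array of another group as to their own. Genes are not independent replicates. The Y-linked genes Eif2s3y, Kdm5d and Uty had signals of 73.2, 47.7 and 51.4 on glioma stem cell array 2. They were 4002.4, 833.8 and 742 on array 3 and 2399.5, 539.8 and 458.1 on array 1, so array 2 was not a technical repeat of either. Xist was 50410.8, 49611.3 and 39079.7 on glioma stem cell arrays 1, 2 and 3, against 587.7 and 385.6 on the NSC arrays numbered 3. Kdm5d was 1273.7 or more on every NSC array. Sex make-up thus differed between arrays and was not adjusted for.

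**Figure D1:**
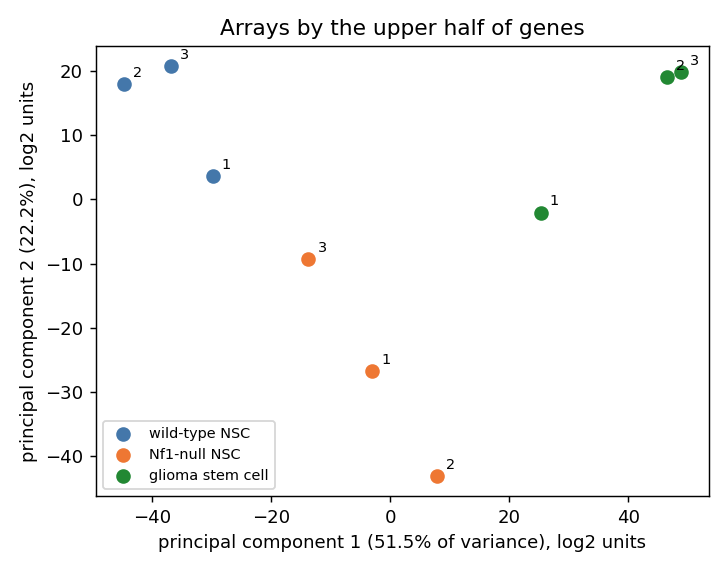
Each point is 1 array, placed by principal components 1 (51.5% of the variance) and 2 (22.2%) of log2 signals of the brighter genes, and numbers give the replicate. Glioma stem cell array 1 sits at 25.28 on the first component, between the Nf1-null NSC and the other glioma stem cell arrays.

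The first question was whether the targeted gene was lowered. Nf1 signal was 1020 ± 111 (SD, n = 3) in wild-type NSC, 551 ± 110 (SD, n = 3) in Nf1-null NSC and 591 ± 37.8 (SD, n = 3) in glioma stem cells. On the individual arrays it was 1139.5, 919.5 and 999.9 in wild-type NSC, 430.3, 645.8 and 577 in Nf1-null NSC, and 622.6, 600.1 and 548.9 in glioma stem cells. The groups did not overlap between wild-type NSC and either other group, and the exact two-sided permutation p was 0.1 for both, the smallest that 3 against 3 arrays allow. That permutation leaves out the pairing of the NSC arrays found in these data. In each same-numbered pair Nf1 was lower in Nf1-null NSC. In the fit across all genes, Nf1 fell in glioma stem cells against wild-type NSC, by 0.78 on the log2 scale (SE 0.19, adjusted p = 0.0441). That call did not hold with quantile normalization (-0.66), with arrays shifted to 1 median (-0.65), with the mean of all probe sets (-0.66), in the 6 arrays compared or with the replicate number as a block (both -0.78). It was also lost without wild-type NSC arrays 1 (-0.70), 2 (-0.86) or 3 (-0.80), glioma stem cell arrays 1 (-0.82), 2 (-0.80) or 3 (-0.73), or Nf1-null NSC array 3 (-0.78). In Nf1-null NSC it was 1.87-fold lower, a log2 difference of -0.90 (SE 0.19, adjusted p = 0.123), which did not pass. Glioma stem cells and Nf1-null NSC differed in Nf1 by 0.12 on the log2 scale (SE 0.19, adjusted p = 0.810). The 2 other Nf1 probe sets were dim, with mean signals of 127.3 and 65.3 in wild-type NSC, 54.4 and 51.8 in Nf1-null NSC and 179.3 and 20.5 in glioma stem cells, and disagreed on the direction in glioma stem cells. The position of the probes relative to the deleted part is not given in the sources used here, so a remaining signal does not measure intact transcript.

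Abcg1, which encodes a cholesterol efflux transporter, rose in glioma stem cells. Its signal was 13008 ± 5215 (SD, n = 3) there, against 1296 ± 496 (SD, n = 3) in Nf1-null NSC and 1714 ± 140 (SD, n = 3) in wild-type NSC. The rise was 9.92-fold over Nf1-null NSC (log2 3.31, SE 0.40, adjusted p = 0.0161) and 7.11-fold over wild-type NSC (log2 2.83, SE 0.40, adjusted p = 0.0128). The call over Nf1-null NSC was lost in the 6 arrays compared (log2 3.31) and without Nf1-null NSC array 3 (3.39), glioma stem cell array 2 (3.08) or array 3 (3.15). The call over wild-type NSC was lost without wild-type NSC array 2 (2.76), glioma stem cell array 2 (2.60) or array 3 (2.67). The gene was named in advance from prior knowledge that may stem from these samples, so its rise is not taken as independent evidence. Nf1-null NSC did not differ detectably from wild-type NSC in Abcg1 (log2 -0.48, SE 0.40, adjusted p = 0.592). Of the other transporters in the fixed list, Abca9 and Abcb1b also rose in glioma stem cells over Nf1-null NSC, by 4.08-fold and 2.82-fold (adjusted p = 0.0340 for Abcb1b), and 33 of 36 did not pass. Both were among the dimmer genes. Against wild-type NSC 4 of 36 rose, among them the drug efflux pump gene Abcg2 (2.61-fold, adjusted p = 0.0114), Abcb8, Abcc5 and Abcd2 fell, and 29 did not pass, with 24 negative. The list was not called over Nf1-null (adjusted p = 0.514) or wild-type NSC (adjusted p = 0.949).

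**Figure D2:**
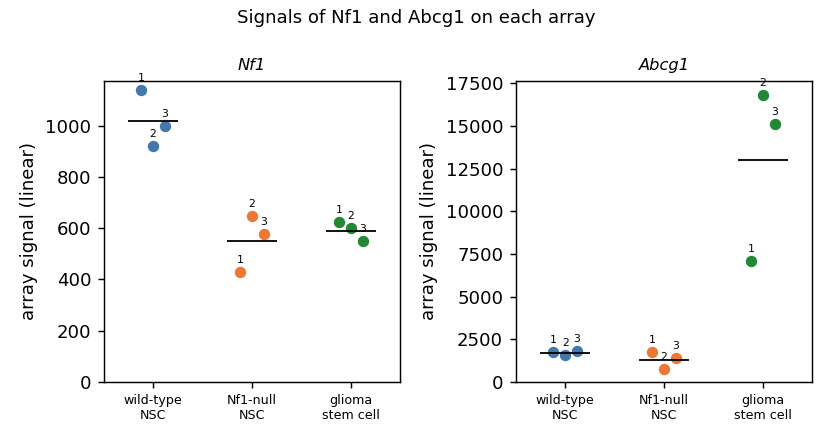
Points are the linear signals of Nf1 (left) and Abcg1 (right) on each array, numbered by replicate, and horizontal lines are group means. Nf1 lies between 919.5 and 1139.5 in wild-type NSC and at 645.8 or less in both other groups, and Abcg1 at 7069 or more in glioma stem cells and at 1823 or less in the NSC.

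Nf1-null NSC were compared with wild-type NSC to ask what differs in these cells after loss of Nf1; the Cre virus and loss of Nf1 went together. No single gene passed when adjusted over all genes in the model without a mean-variance trend, and no list call held with an estimated correlation between genes. Cell cycle genes had a median of 3.61-fold in Nf1-null over wild-type NSC, with all 43 measured members positive (list adjusted p = 1.79e-22, and adjusted p = 0.424 with an estimated correlation). Ccnd1, which encodes cyclin D1, had a signal of 33425 ± 4729 (SD, n = 3) against 5274 ± 2863 (SD, n = 3), a 7.23-fold difference, and Ccnd2 differed 3.76-fold. Targets and feedback regulators of ERK signalling had a median of 2.04-fold, with 21 of 24 members positive (list adjusted p = 1.2e-10, and adjusted p = 0.424 with an estimated correlation). Dusp6, an ERK phosphatase, differed 5.06-fold and the transcription factor gene Etv5 2.59-fold. Immediate early genes had a median of 2.30-fold with 22 of 26 positive (list adjusted p = 8.11e-10, and adjusted p = 0.424 with an estimated correlation), among them Egr3 (6.34-fold), Dusp1 (3.36-fold) and Fos (2.97-fold). The ratio of 3' to 5' signal of Actb, a control for RNA quality, was 1.87 to 1.88 in wild-type NSC, 1.49 to 1.67 in Nf1-null NSC and 1.73 to 1.85 in glioma stem cells, so it also separated the groups compared.

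All 20 measured oligodendrocyte precursor genes were negative, with a median of 0.541 of the wild-type NSC level (list adjusted p = 3.64e-07, and adjusted p = 0.424 with an estimated correlation). Examples were Pcdh15 (4.23-fold lower), Lhfpl3 (3.97-fold lower) and Sox6 (3.39-fold lower), and Pdgfra, the receptor that marks these precursors, had a log2 difference of -2.87 (SE 0.85). Of 23 astrocyte genes, 21 were negative, with a median of 0.481 of the wild-type NSC level (list adjusted p = 0.000119, and adjusted p = 0.503 with an estimated correlation). Aqp4, the astrocyte water channel, was 4.62-fold lower and Apoe 2.07-fold lower. Hypoxia and glycolysis genes had a median of 1.67-fold with 26 of 32 positive, such as Pfkfb3 (3.18-fold; list adjusted p = 2.96e-05, and adjusted p = 0.588 with an estimated correlation). The groups overlapped in that list, with array medians of -0.01, 1.09 and 1.05 on the log2 scale in Nf1-null NSC and -0.62, 0.11 and 0.60 in wild-type NSC. These are in order of replicate number, and in each same-numbered pair the Nf1-null NSC array was the higher. Cholesterol synthesis genes had a median of 1.43-fold with 16 of 20 positive, such as Stard4 (1.68-fold; list adjusted p = 7.95e-05, and adjusted p = 0.503 with an estimated correlation). Array medians overlapped here too, at 0.51, 0.17 and 0.70 against 0.18, -0.22 and 0.02, again with the Nf1-null NSC array higher in each same-numbered pair. The p53 targets had a median of 1.11-fold with 16 of 24 positive, such as Cdkn1a (2.67-fold; list adjusted p = 0.0204, and adjusted p = 0.424 with an estimated correlation).

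In the limma fit of all 18193 genes without a mean-variance trend, no gene passed an adjusted p of 0.05 between Nf1-null and wild-type NSC. The smallest adjusted p was 0.0734, that of Tubb6, a tubulin gene that was 6.13-fold higher. At an unadjusted p under 0.05 there were 3048 genes, where 910 would come by chance, and the 3 against 3 values did not overlap for 23.8% of genes, where chance gives 10%. The planned ordinary (unmoderated) per-gene linear-model test also gave 0 genes, while the planned fits of all genes with a mean-variance trend gave 329, and 378 with robust moderation as well. Without the dimmest 25% of genes 136 passed. When only the brighter 9097 genes were tested, an alternative planned in advance, 398 genes passed, 208 higher and 190 lower. With the replicate number as a block as well, 1081 passed in the 9 arrays and 754 in the 6 arrays compared. Those combinations were chosen after seeing the data, and the block alone gave 0.

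The largest rises among those 398 genes, named by the fixed rule applied to that test after the data were seen, were Akap12 (10.7-fold, adjusted p = 0.0147, against 0.0825 over all genes), Cd93 (10.6-fold), Gap43 (8.36-fold), Ier3 (8.01-fold) and Ccnd1 (7.23-fold). Angpt2, Plvap, Egr3, Tubb6 and Pf4 followed, at 6.84-fold to 6.09-fold. Akap12 encodes a kinase scaffold and Gap43 a growth cone protein. The largest falls were Kcnd2 (8.73-fold, adjusted p = 0.0252, against 0.109 over all genes), Slc1a1 (7.26-fold), Plppr1 (6.54-fold), Ryr3 (6.17-fold) and Myt1 (5.63-fold). Pcdh10, Srpk3, Gabbr1, Snap91 and Id4 followed, at 5.38-fold to 4.46-fold. Kcnd2 encodes a potassium channel, Slc1a1 a glutamate transporter, and Id4 an inhibitor of basic helix-loop-helix factors. In this test of the brighter genes, Nf1 also passed (adjusted p = 0.0285).

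The list test with a preset correlation called 8 of 37 lists between Nf1-null and wild-type NSC, and the rotation test fry and the test with an estimated correlation called 0. Adjusted over the list alone, 39 of 43 cell cycle genes rose, 16 of 24 ERK output genes rose and 1 fell, and 11 of 26 immediate early genes rose. On the same basis 9 of 20 oligodendrocyte precursor genes and 0 of 23 astrocyte genes fell. Adjusted over all genes, none passed in any list without the mean-variance trend. With it 6 of 43 cell cycle genes and 5 of 26 immediate early genes rose, 8 of 24 ERK output genes rose and 1 fell, and 1 of 20 oligodendrocyte precursor genes and 0 of 23 astrocyte genes fell.

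**Figure D3:**
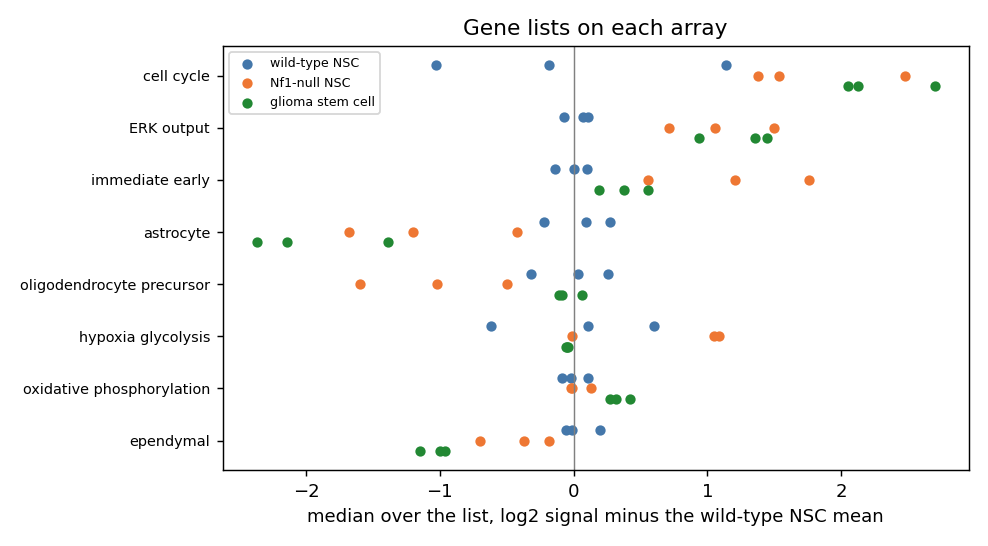
Each point is the median over the members of a gene list on 1 array, as log2 signal minus the wild-type NSC mean of each gene, with colours for the 3 groups. Cell cycle medians lie between 1.38 and 2.48 in Nf1-null NSC and between 2.05 and 2.70 in glioma stem cells, while the wild-type NSC arrays spread from -1.03 to 1.14.

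Glioma stem cells were next compared with Nf1-null NSC, to find what sets the tumour-derived cells apart from stem cells that also lost Nf1. Aldh1l1, an enzyme gene used as a pan-astrocyte marker, fell 90.7-fold (adjusted p = 0.00241), from a signal of 32869 ± 7554 (SD, n = 3) to 394 ± 232 (SD, n = 3). Aqp4 fell 33.3-fold (adjusted p = 0.0205) and Gja1, a gap junction protein gene, 5.46-fold (adjusted p = 0.0346). S100b went the other way, at 5.49-fold higher, without passing (adjusted p = 0.0809). In the astrocyte list 3 of 23 genes fell, 0 rose and 20 did not pass, with 17 negative and a median of 0.501 of the Nf1-null NSC level. The list test gave an adjusted p of 0.000422 (adjusted p = 0.670 with an estimated correlation). Against the wild-type NSC mean, the list's median was -1.39 on the log2 scale on glioma stem cell array 1 and -2.14 and -2.37 on arrays 2 and 3.

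Oligodendrocyte precursor genes were mostly higher in glioma stem cells than in Nf1-null NSC, with 17 of 20 positive, a median of 1.97-fold and an adjusted p of 3.39e-06 (adjusted p = 0.670 with an estimated correlation). Against wild-type NSC the same list was not called (adjusted p = 0.985), with 9 positive, 11 negative, 0 that rose and array medians of -0.09, 0.06 and -0.11 on the log2 scale. Against Nf1-null NSC Pcdh15 rose 12.1-fold (adjusted p = 0.0281) and Lhfpl3 5.56-fold (adjusted p = 0.0391), while Emid1 fell 16.5-fold (adjusted p = 0.0335). Among myelin and mature oligodendrocyte genes, Bcas1 rose 6.73-fold and Ppp1r14a 10.2-fold, Opalin fell 2.91-fold, and 18 of 21 did not pass. Ppp1r14a had signals of 6.3, 18.5 and 11.7 in Nf1-null NSC, so its fold depends on the pseudocount. That list had an adjusted p of 0.00583 (adjusted p = 0.670 with an estimated correlation), and it was not called against wild-type NSC (adjusted p = 0.496). Mbp, the myelin basic protein gene, was 61.3-fold higher (log2 5.94, SE 1.30, adjusted p = 0.0799) without passing. It was uneven between the glioma stem cell arrays, at 2601.3, 29057.3 and 65239.2.

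The largest rises in glioma stem cells over Nf1-null NSC were Brinp3 (48.4-fold), St6gal2 (29.5-fold), Gabra2 (21.4-fold), Neurod1 (20.0-fold), Casp12 (16.9-fold) and Gria4 (14.7-fold). In Nf1-null NSC, Brinp3 had signals of 219.5, 16.8 and 211.8, and St6gal2 had 483.7, 38.4 and 227. The folds of these 2 genes lean on the low signals of array 2 and are uncertain. In wild-type NSC, signals were 823.5 or more for Brinp3 and 444.3 or more for St6gal2. Gabra2 and Gria4 encode neurotransmitter receptor subunits, and Neurod1 is a neuronal transcription factor gene. The fixed list of neuroblast and neuron genes was not called (adjusted p = 0.153), with 2 of 31 that rose, 0 that fell and 29 that did not pass. Gria4 and Neurod1 did not differ detectably between the NSC groups, while Brinp3 was lower in Nf1-null than in wild-type NSC without passing (log2 -3.50, SE 0.90, adjusted p = 0.165). Rbfox1, Pcdh15, Itga8 and Gal followed, at 12.2-fold to 11.1-fold. The largest falls were Fbln2 (675-fold), Otx2 (377-fold), Cybrd1 (115-fold), Aldh1l1, Car8 (41.8-fold) and Serpinh1 (38.7-fold). Fbln2 encodes a matrix protein, Serpinh1 a collagen chaperone, and Otx2 a transcription factor of the embryonic forebrain and midbrain. Fbln2 had signals of 290.2, 14.1 and 19.6 on the glioma stem cell arrays, and its log2 difference moved from -9.40 to -10.75 without array 1 and to -7.21 with the mean of its probe sets, so its fold is uncertain. Otx2 went from 1968 ± 953 (SD, n = 3) to 4.1 ± 2.4 (SD, n = 3), which is at the low end of the arrays, so the size of that fold depends on the pseudocount of 1. Ecm2, Fndc3c1, Aqp4 and Pcp4l1 completed the 10 largest falls, at 36.6-fold to 30.7-fold. Folds are uncertain where a group's mean log2 signal was under 6.41, the limit of the dimmest 25% of genes. These were Abca9, Ppp1r14a and Rbfox1 for Nf1-null NSC, and Ecm2, Emid1, Ereg, Fbln2, Otx2 and Tgfb3 for glioma stem cells.

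Lists of growth factors and receptors (42 of 46 not passing), of TGF-beta and BMP signalling (26 of 29) and of matrix and adhesion genes (40 of 45) were not called but held genes that changed. Among growth factor and receptor genes, Pdgfa rose 6.96-fold, while Igf1 (12.1-fold), Ereg (8.01-fold) and Mdk (6.71-fold) fell. Tgfb2 rose 4.65-fold and Bmp7 2.68-fold, and Tgfb3 fell 14.2-fold. The matrix genes Mmp14 (9.20-fold), Timp1 (9.50-fold) and Thbs2 (8.61-fold) fell and Mmp16 rose 3.77-fold. In the neural stem cell list, Emx2 (6.23-fold), Sox1 (8.22-fold) and Hopx (3.71-fold) fell, and 22 of 25 did not pass (list adjusted p = 0.0155, and adjusted p = 0.670 with an estimated correlation). Of the ependymal genes Dynlrb2 (5.53-fold) and Pltp (2.04-fold) fell and 21 of 23 did not pass (list adjusted p = 0.000225, and adjusted p = 0.346 with an estimated correlation). Of the imprinted genes Peg3 (5.91-fold) and Grb10 (13.5-fold) fell and 18 of 20 did not pass (list adjusted p = 0.0192, and adjusted p = 0.416 with an estimated correlation). Fos fell 2.99-fold (adjusted p = 0.0488), to a glioma stem cell level with a log2 difference of -0.01 from wild-type NSC (SE 0.29).

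In all, 319 of 18193 genes passed an adjusted p of 0.05 in limma between glioma stem cells and Nf1-null NSC, 122 higher and 197 lower. Of these, 129 were among the dimmer genes. With the replicate number as a block in the 9 arrays 193 passed, and with the block in the 6 arrays compared 0 passed. The 6 arrays compared gave 29 when fitted alone. The count was 721 without glioma stem cell array 1, 74 and 77 without arrays 2 and 3 of that group, 83, 105 and 72 without Nf1-null NSC arrays 1, 2 and 3, and 147, 118 and 155 without wild-type NSC arrays 1, 2 and 3.

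The list test called 10 of 37 lists between glioma stem cells and Nf1-null NSC, and none held with an estimated correlation. Oxidative phosphorylation genes had an adjusted p of 2.12e-11 (adjusted p = 0.670 with an estimated correlation), with all 42 members positive, a median of 1.25-fold and 0 past the threshold. Cell cycle genes had 0.00039 (adjusted p = 0.725 with an estimated correlation), with all 43 positive, a median of 1.40-fold and 0 past the threshold. Array medians of the cell cycle, astrocyte, mature oligodendrocyte and neural stem cell lists overlapped between the groups. Downward lists with 1 member or none past the threshold were hypoxia and glycolysis at 0.000239 (adjusted p = 0.671 with an estimated correlation), with array medians of -0.05, -0.06 and -0.04 against -0.01, 1.09 and 1.05, and immediate early genes at 0.0192 (adjusted p = 0.671 with an estimated correlation). The rotation test fry called the ependymal (adjusted p = 0.0117) and imprinted (adjusted p = 0.0281) lists. Adjusted over the list alone, 8 oligodendrocyte precursor genes rose and 1 fell, while 8 astrocyte genes fell and 1 rose, and 7 ependymal genes fell.

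**Figure D4:**
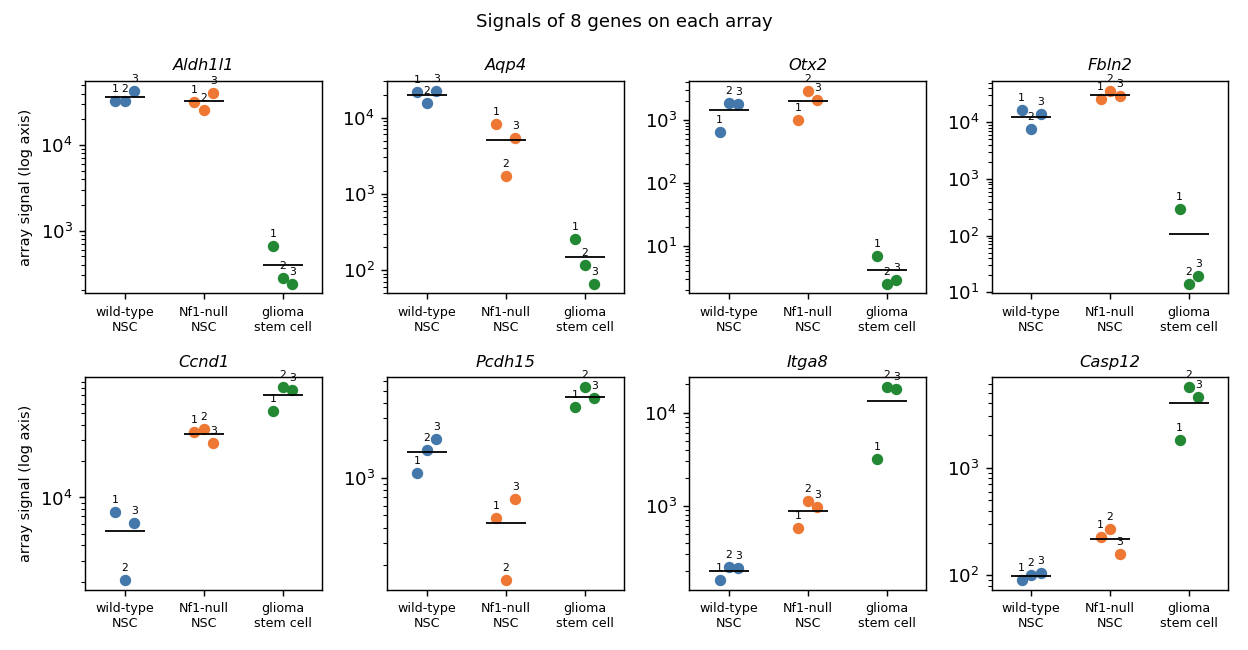
Points are signals of 8 genes on each array on a log axis, numbered by replicate, with horizontal lines at the group means. Aldh1l1, Aqp4, Otx2 and Fbln2 are lowest on the glioma stem cell arrays, and Ccnd1, Pcdh15, Itga8 and Casp12 are highest there.

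Glioma stem cells against wild-type NSC showed more changes. The cell cycle list had 19 of 43 genes that rose, 0 that fell and 24 that did not pass, with all 43 positive, a median of 4.75-fold and a list adjusted p of 4.77e-23 (adjusted p = 0.575 with an estimated correlation). Ccnd1 rose by 3.91 on the log2 scale (adjusted p = 0.00953) to a signal of 70473 ± 16353 (SD, n = 3), and Ccnd2, Gins2 and Cdt1 rose 4.65-fold, 3.85-fold and 9.48-fold. Of 24 ERK output genes, 13 rose, with Dusp6 at 7.34-fold, Spry4 at 15.2-fold and Dusp4 at 26.5-fold. Epha4 alone in that list fell, 5.14-fold, and 10 did not pass (list adjusted p = 8.92e-10, and adjusted p = 0.439 with an estimated correlation). Astrocyte genes fell in 13 of 23 cases, including Aqp4 (154-fold), Aldh1l1 (101-fold), Gja1 (9.40-fold) and Clu (4.63-fold), and 0 rose (list adjusted p = 1.41e-07, and adjusted p = 0.575 with an estimated correlation).

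Of 23 ependymal genes 8 fell, among them Pltp (3.68-fold), Dynlrb2 (7.76-fold) and the ciliary regulator gene Rfx3 (4.22-fold), and 0 rose (list adjusted p = 2.7e-05, and adjusted p = 0.244 with an estimated correlation). The neural stem cell list had 8 genes that fell, with Id4 (9.62-fold), Sox1 (15.2-fold), Emx2 (3.57-fold) and Lrig1 (1.82-fold) leading, 2 that rose and 15 that did not pass (list adjusted p = 0.0311, and adjusted p = 0.760 with an estimated correlation). In the Notch list Hey1 (2.90-fold) and Notch2 (4.06-fold) fell, Hey2 fell by 3.33 on the log2 scale, Hes1 rose 1.84-fold, and 19 of 23 did not pass (list adjusted p = 0.00648, and adjusted p = 0.575 with an estimated correlation). In the Wnt list Lgr5 (4.49-fold) and Fzd1 (7.49-fold) rose while Nkd2 (4.41-fold) and Wnt5b (3.87-fold) fell, and 25 of 32 did not pass (list adjusted p = 0.0311, and adjusted p = 0.760 with an estimated correlation). The p53 targets Eda2r (2.34-fold), Aen (1.81-fold) and Cdkn1a (4.49-fold) rose, Cdkn1c fell 5.64-fold, and 18 of 24 did not pass (list adjusted p = 0.00255, and adjusted p = 0.523 with an estimated correlation). Cholesterol synthesis genes that rose were Hsd17b7 (3.11-fold), Sqle (1.77-fold) and Insig1 (2.34-fold), and 17 of 20 did not pass (list adjusted p = 0.000437, and adjusted p = 0.760 with an estimated correlation). Atp5g1, Cycs and Ndufa4 of oxidative phosphorylation rose 1.94-fold, 2.22-fold and 1.45-fold and 39 of 42 did not pass (list adjusted p = 9.58e-11, and adjusted p = 0.575 with an estimated correlation). Jun, Klf6, Dusp1 and Ier3 of the immediate early list rose 2.82-fold to 9.57-fold and 22 of 26 did not pass (list adjusted p = 0.0120, and adjusted p = 0.760 with an estimated correlation).

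Among all genes, the largest rises over wild-type NSC were Clic5 (114-fold), Apod (75.6-fold), Itga8 (51.8-fold), Hpse (42.8-fold), Akap12 (39.4-fold), Casp12 (36.2-fold) and Cd93 (32.4-fold), followed by Ppp1r14a, Dusp4 and Aldh1a3. Folds of Clic5, Apod, Hpse, Ppp1r14a and Aldh1a3 are uncertain, as their mean log2 signal in wild-type NSC was under 6.41, as are those of Otx2, Otx1, Paqr7, Kcne1l and Rnase1 for glioma stem cells and of Hoxb9 and Hoxc8 for both groups. The signal of Apod, an apolipoprotein gene, was 8569 ± 9992 (SD, n = 3) in glioma stem cells, a spread wider than its mean. The largest falls were Fbln2 (269-fold), Otx2 (268-fold), Aqp4, Cybrd1 (114-fold), Camk2a (113-fold), Aldh1l1 and Paqr7 (97.6-fold), followed by Kcne1l, Rnase1 and Sncaip. The glioma stem cell signals of Camk2a were 243.3, 1.5 and 20.5 and its log2 difference moved from -6.81 to -2.68 with the mean of its probe sets, so its fold and rank are uncertain, as are those of Fbln2, at 290.2, 14.1 and 19.6. Of 56 forebrain and diencephalon regional genes 4 fell, among them Otx2 and Otx1 (19.9-fold), 0 rose and 52 did not pass, and the list was not called (adjusted p = 0.801). Of 31 neuroblast and neuron genes 3 rose, 4 fell, among them Neurog2 and Rbfox3 (6.26-fold), and 24 did not pass (list adjusted p = 0.974). Of 33 Hox genes Hoxa3 and Hoxa5 rose 4.08-fold and 4.58-fold, Hoxb9 and Hoxc8 fell by 1.58 and 2.14 on the log2 scale, and 29 did not pass (list adjusted p = 0.639).

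Limma called 1649 of 18193 genes between glioma stem cells and wild-type NSC, 630 higher and 1019 lower, against 831 higher and 695 lower with arrays shifted to 1 median and 740 and 857 with quantile normalization, so which direction had more genes depended on the scaling. The shift to 1 median moved the median gene by 0.14 on the log2 scale. Of the 1649 genes, 517 were among the dimmer genes. With the replicate number as a block 1536 passed in the 9 arrays and 0 in the 6 arrays compared. The count was 878, 214 and 458 without wild-type NSC arrays 1, 2 and 3, and 217 and 262 without glioma stem cell arrays 2 and 3. Without glioma stem cell array 1 it was 1756. Over all comparisons, 122 of 159 named results that passed were lost in at least 1 of the alternatives followed for named genes, and 0 changed sign. The block in 6 arrays was not among those alternatives, and with it all 159 were lost.

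The list test called 11 of 37 lists between glioma stem cells and wild-type NSC, 6 upward and 5 downward, and none held with an estimated correlation. Of these, array medians overlapped between the groups for the neural stem cell list. The rotation test fry called 8 of these 11. Adjusted over the list alone, 41 cell cycle genes and 9 cholesterol synthesis genes rose, 17 ERK output genes rose and 1 fell, 15 astrocyte genes fell and 1 rose, and 11 ependymal genes fell.

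The changes of the Nf1-null NSC and of the glioma stem cells, both taken against the same wild-type NSC arrays, were also compared. No gene was called in both among all genes, because none was called in Nf1-null NSC without the mean-variance trend. At an unadjusted p under 0.01 in both, 268 genes were higher in both, 264 lower in both and 10 opposite. Simulated unchanged groups against shared controls gave means of 20.6 higher in both and 20.6 lower in both, and independent lists would share 23.5 and 41.4. Those groups were simulated as independent; with a part shared by same-numbered wild-type and Nf1-null NSC arrays, as strong as observed and added after seeing the data, the means were 15.6 and 14.9. In the test of the brighter genes alone, 298 were called in both, 160 higher and 131 lower in both and 7 opposite. Independent lists would share 23.8 and 29.9. The simulation of independent groups gave 0, but it held no changed gene, so its 0 is no baseline for sharing. At an unadjusted p under 0.01 it also had fewer genes to share, with means of 195 and 197, against 972 and 2396 observed. Across genes the 2 sets of fold changes correlated at 0.56, where simulation without effects gave 0.50 and 0.47 with the shared part. Their covariance was 0.394 against 0.173 and 0.153 simulated, and for the brighter genes 0.30 against 0.0394 and 0.0195. Both simulations already used shared controls, with genes simulated as independent, so the excess is beyond that part. Real genes are not independent replicates, and 3 controls cannot be split into sets of 2. Deviations of the controls that many genes share were not simulated, so a part from the shared controls stays open.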

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

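The tests of dim probe sets, of few genes differing, of the block, of a compressed array, of arrays numbered 1, of single culture pairs and of the Cre virus were chosen after their results, or results close to them, had been seen, and the bound in the test of a compressed array was replaced after its first result. The model was also run on 10092 probe sets with no gene symbol or several, which the comparisons of genes do not use. Among them 24 changed between glioma stem cells and Nf1-null NSC and 52 between glioma stem cells and wild-type NSC; limma called 0 between the NSC groups, with 1025 at an unadjusted p under 0.05.

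No gene passed between Nf1-null and wild-type NSC in limma when all genes were tested without a mean-variance trend, while 329 passed with the trend and 378 with trend and robust moderation. The tables argue against few genes differing: 3048 genes had an unadjusted p under 0.05, where 910 would come by chance. The other splits of the 6 arrays that part all 3 same-numbered pairs gave at most 548, and any other split at most 1842. Those splits mix the groups, so real differences widen the spread within their sides and lower their counts. The size of that gap is therefore no measure of how many genes differ. The tables also argue against hidden culture differences as the whole cause, since the brighter genes gave 398 calls without the block. The block in 9 arrays gave 0 calls over all genes. That block also ties the glioma stem cell arrays to the NSC arrays of the same number, so its 0 cannot decide. Noise of dim probe sets is a candidate explanation, since those 398 calls compare with at most 4 in 100 random sets of as many genes. A part played by culture differences stays open, as adding the block in 9 arrays raised the 398 calls to 1081. Over all genes with the trend, the block in 6 arrays gave 1018 calls, a combination chosen after seeing the data. Biology stays open as well, since virus and genotype moved together.

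Glioma stem cell array 1 lay nearer to the NSC than arrays 2 and 3. Admixed NSC would bring their abundant transcripts. Yet 15 genes high in arrays 2 and 3, such as Itga8, Gria4, Pdgfa, Fgf1 and Abcg1, would need a median NSC share of 77.5%. The 11 genes high in the NSC, such as Aldh1l1, Fbln2 and Aqp4, showed 1.3%. Both sets are small. They were chosen without array 1, which favours genes on which array 1 lies nearer to the NSC. The spread of log2 signals on array 1 was 0.978 of that of arrays 2 and 3, and its relative SD over the 9 arrays was 0.021. Compression alone would need a ratio of 0.008 for those 15 genes, an array with almost no spread. No array could have shown that, with SDs of 1.559 to 1.649, so this test cannot decide. A partial compression was not tested. The NSC arrays numbered 1 explained 8.7% of the variance of the deviation of glioma stem cell array 1, which argues against a difference shared by arrays of that number as the whole cause. A different tumour or state of the culture was not tested and may remain.

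Cell cycle genes were higher in Nf1-null than in wild-type NSC. A bias that depends on signal is argued against by the list's median, which lay at percentile 100 of 10000 random lists matched on mean signal, the highest of which reached 0.22 on the log2 scale. A single culture pair is argued against as well, since the smallest of the 3 same-numbered median differences was 1.29 and the largest 2.64. The Cre virus itself and loss of Nf1 cannot be told apart, since 0 arrays had the Cre virus with intact Nf1. Loss of Nf1 is therefore a hypothesis that could be tested with such a control, and a difference in RNA quality, which the Actb ratios leave open, was not tested.

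The 6 arrays of a comparison allow 10 splits, too few for a share under 0.05. All splits but the real one mix the groups, so real differences widen the spread within their sides and lower their gene counts. The highest other counts of genes are therefore low in part by construction. For glioma stem cells against Nf1-null NSC, 1 of 10 splits gave as many as the real 319 genes, the real split itself, and the highest other gave 2. Against wild-type NSC it was also 1 of 10, with 1649 genes and 2 in the highest other. For Nf1-null against wild-type NSC all 10 splits gave at least the real count of 0 genes, with 1 in the highest other. Among the brighter genes 1 of 10 gave as many as 398, with 0 in the highest other, including the other splits that part all 3 pairs. For lists, 3 of 10 splits gave as many in each comparison. The real list counts were 8, 10 and 11 and the highest others 9, 13 and 15, so the list test with a preset correlation also called lists between arrays mixed across groups. For lists, the highest other split in each comparison set arrays 1 and 2 of the reference NSC group together with array 1 of the other group.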

How the results depend on the processing

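The settings that combine 2 or more choices, the lists with a pseudocount of 16 or only brighter genes, and Nf1 with only brighter genes were chosen after seeing the data. Filters on dim genes also test fewer genes. For Nf1-null against wild-type NSC, 100 random sets as large as the brighter genes gave at most 4 calls, against 398 for the brighter genes. Fewer tests alone therefore did not give that count. Fits of 6 arrays use fewer arrays. For the other settings the cause was not tested.

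For Nf1-null against wild-type NSC, 0 genes became 136 without the dimmest 25% of genes, 398 with only the brighter genes, 329 with a mean-variance trend and 378 with trend and robust moderation. With only brighter genes, adding the trend gave 518, the replicate block in 9 arrays 1081, the block in 6 arrays 754, trend and block in 6 arrays 1180, and leaving out glioma stem cell array 1 590. The trend with the block in 6 arrays gave 1018. Leaving out 1 array gave 0 to 1.

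For glioma stem cells against Nf1-null NSC, 319 genes became 149 with the mean of all probe sets, 536 without the dimmest 25%, 607 with only the brighter genes, 737 with the trend, 773 with trend and robust moderation and 973 with array weights. The count was 29 in the 6 arrays compared, 138 unmoderated, 21 at an adjusted p under 0.01, 193 with the replicate block in 9 arrays and 0 with it in 6. With only brighter genes, adding the trend gave 625, the block in 9 arrays 944, the block in 6 arrays 323, trend and block in 6 arrays 405, and leaving out glioma stem cell array 1 1241. The trend with the block in 6 arrays gave 497. Leaving out 1 array gave 72 to 721.

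For glioma stem cells against wild-type NSC, 1649 genes became 1083 with the mean of all probe sets, 2488 without the dimmest 25%, 2680 with the trend, 2767 with trend and robust moderation, 3515 with array weights, 1030 in 6 arrays and 125 at an adjusted p under 0.01. With 630 higher and 1019 lower at first, arrays shifted to 1 median gave 831 higher and 695 lower and quantile normalization 740 and 857. The replicate block in 6 arrays gave 0. With only brighter genes, adding the trend gave 2531, the block in 9 arrays 3013, the block in 6 arrays 2541, trend and block in 6 arrays 2730, and leaving out glioma stem cell array 1 2606. The trend with the block in 6 arrays gave 2787. Leaving out 1 array gave 214 to 1756.

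With an estimated correlation 0 lists were called in each comparison, and with fry 0 in Nf1-null against wild-type NSC and 2 in glioma stem cells against Nf1-null NSC. Leaving out 1 array gave 6 to 11, 8 to 14 and 9 to 13 lists. Over the fits with 1 array left out, 69 results of called lists passed and 3 were lost between the NSC groups. For glioma stem cells these were 84 and 6 against Nf1-null NSC, and 90 and 9 against wild-type NSC. With only the brighter genes, 1 called list was lost against Nf1-null NSC and 2 against wild-type NSC. The mean of all probe sets lost the same numbers. No called list changed direction in the alternatives run on it, and with the replicate block in 9 arrays every called list passed.

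Nf1 in glioma stem cells against wild-type NSC did not pass with quantile normalization (-0.66), arrays shifted to 1 median (-0.65), the mean of all probe sets (-0.66), the 6 arrays compared (-0.78) or the replicate block in 9 arrays (-0.78); leaving out 1 array gave -0.86 to -0.70. Between Nf1-null and wild-type NSC it passed with only the brighter genes (-0.90) and in no other alternative run on it. Between glioma stem cells and Nf1-null NSC, leaving out 1 array gave -0.05 to 0.24, negative only without Nf1-null NSC array 1. Genes shared by both comparisons against wild-type NSC numbered 97 without the dimmest 25%, 532 at an unadjusted p under 0.01 in both, and 0 to 1 with 1 array left out.

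Named results were followed through both other scalings, the mean of all probe sets, the trend, the 6 arrays compared, the block in 9 arrays and each array left out. Of 159 that passed, 37 passed in all of these and 122 were lost in at least 1. Of the 122, 45 were lost only when an array was left out, and 0 changed sign. The block in 6 arrays was not among these alternatives, and all 159 were lost with it, as 0 genes passed. With the replicate block in 9 arrays, 18 were lost between glioma stem cells and Nf1-null NSC and 20 between glioma stem cells and wild-type NSC. The folds of dimmer genes are the least certain, as the median spread between replicates was 1.12 on the log2 scale in the dimmest bin of genes and 0.20 in the brightest.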

Other observations

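The set of 15 genes high on glioma stem cell arrays 2 and 3 was chosen after array 1 had been seen to stand apart. Several fixed lists were not called by the list test in any comparison but held genes that changed. Among interferon-stimulated genes Gbp2 fell 12.2-fold in glioma stem cells against wild-type NSC (adjusted p = 0.00203), from 708 ± 163 (SD, n = 3) to 56.5 ± 7.7 (SD, n = 3), and Mx2 also fell, by 2.26 on the log2 scale, while Ifi27 rose 3.64-fold and Ifi35 rose by 1.59, and 30 of 34 did not pass. Antigen presentation genes went both ways, with B2m up 2.08-fold and Tap1 up 1.69-fold, H2-K1 down 2.11-fold and Tapbp down 2.52-fold, and 12 of 16 did not pass. Markers of Schwann and neural crest cells included Cdh19 (7.29-fold), Pou3f1 (3.20-fold) and Dhh (5.05-fold), which rose in glioma stem cells against wild-type NSC, with 14 of 17 not passing. In the Hedgehog list Gli1 and Gli2 fell 5.31-fold and 3.43-fold, Foxf1 rose 6.23-fold and Gas1 1.92-fold, and 12 of 16 did not pass. The folds of Gbp2, Gli1 and Mx2 are uncertain, as their mean log2 signal in glioma stem cells was under 6.41. Of 26 microglia and macrophage genes, all among the dimmer genes, limma called 0 in the 2 comparisons with Nf1-null NSC and 1 against wild-type NSC, Siglech, which fell by 0.82 on the log2 scale.

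The genes that set glioma stem cell arrays 2 and 3 furthest above the NSC also differed within the glioma stem cell group. Their choice left out array 1, which favours genes lower on that array, so part of this difference is built in. At 8-fold or more among the brighter genes, the chosen genes numbered 15, led by Mbp, Itga8, Gria4, Pxdc1 and Lpl. Abcg1 was among them, at 7069.3 on array 1 against 16841 and 15114.7 on arrays 2 and 3. Pdgfa was at 3598.9 against 12306.2 and 12940.5. Array 1 was above every NSC array for Itga8, Gria4, Abcg1 and Pdgfa, but not for Mbp, where wild-type NSC array 3 had 6599.4 and array 1 had 2601.3.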
